A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

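RNA polymerase II ChIP-chip was measured on 4 Agilent tiling arrays, 2 at 0 min and 2 at 60 min after the shift to galactose, each with an immunoprecipitate and genomic DNA in different dyes, per the labels. The deposited scanner output holds spot intensity in both channels and, per the file headers, was made with Feature Extraction 9.1.3.1 under a CGH protocol with spatial and multiplicative detrending, without local background subtraction, and with a linear dye normalization. The deposited log10 ratio of Cy5 over Cy3 of each spot was not used for any value. The deposited value table holds log2 ratios, and each column equals log2 of Cy3 over Cy5 of the processed intensities of its array, with slope 1 and a largest difference of 1.43e-05, so it was not centred further (column medians -0.091, -0.076, -0.07 and -0.066). Why the table runs this way is not stated in the sources used here. All 4 arrays lie on 1 slide and came from 1 scan, so slide and scan do not separate the arrays, while the place of an array on the slide cannot be told apart from the time point.

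The labels give Cy5 for the immunoprecipitate and Cy3 for genomic DNA, and the ratio was planned as Cy5 over Cy3 before the data were examined. The deposited table runs the opposite way. After the values were seen, the reported orientation was changed to Cy3 over Cy5, because the change of the galactose genes lay in Cy3 and the deposited table runs this way. The planned orientation gives the same sizes and p-values of the ratios with the opposite sign, and its values are among the alternatives.

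Per probe, log2 of the processed Cy3 over Cy5 intensity was taken, control spots and spots with a non-uniformity or population outlier flag in either channel (1.33 to 2.46% per array) were left out, and each array was centred on its median. No loess or quantile normalization was used, since most probes of a ChIP array carry signal. Saturated spots (298 to 354 per array in Cy5 and 0 to 70 in Cy3) were kept. Raw medians stood 295.5 to 331.5 times above the local background in Cy5 and 46.3 to 75.0 times in Cy3. Values were averaged over the probes inside each ORF as the files name them, with at least 1 probe and a median of 5. Of the 5492 names, 5469 matched a gene table of the R64 assembly, which was used for names, strand and coding length and for no coordinates, and 23 kept the name in the files. The genome build of the probe coordinates is not given in the sources used here. Position classes were those of the files, in place of the planned classes, because no annotation of that build was used here. Names absent from the gene table were treated as dubious in the choice of named genes.

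Time points were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3) over 4 arrays with the group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with at least 4 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, over ORFs measured on all 4 arrays, with adjustment over the 31 lists. List levels were set against 10000 random lists of the same size. For the difference along genes, the span of the probes in an ORF was divided into 3 equal parts, and the mean of probes in the 5′ part was subtracted from that in the 3′ part in ORFs of at least 1500 bp. Named genes were fixed by rule before the data were examined: every measured member of the galactose list; up to 10 ORFs per direction with the largest difference among those past the threshold whose groups do not overlap, dubious ORFs left out; up to 4 members with the largest absolute difference of each list described; and the 10 ORFs with at least 2 probes and the highest mean at each time point, dubious ORFs left out. The values of 1 gene that this rule names are not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

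The alternatives covered background correction by normexp with an offset of 50, loess, quantile normalization, no centring, a filter on dim probes, spots with outlier flags kept, at least 3 probes per ORF, the median over probes, Cy5 alone, the deposited table, eBayes with trend and robust, replicate number as a block, ORFs of at least 2000 bp for the difference along genes, and each array left out. Cy5 alone is given with its sign turned to match the reported direction. A block for slide or scan was not run, with 1 slide and 1 scan. Cy3 alone, scaling between arrays, crossed replicate numbers and leaving out mitochondrial probes were added after seeing the data. The functions were tested on simulated data for the gene comparison, in 20 runs over 5451 ORFs with 200 changed per run and variances drawn from the fitted prior. At a log2 change of 0.5 the fit recovered 3.3% of changed ORFs, at 1 it recovered 64.5%, at 2 it recovered 94.0% and at 4 it recovered 99.4%, with a mean of 7.1 false calls per run. The simulation gave both time points equal variance, which the arrays do not have.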

Results

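RNA polymerase II occupancy was profiled across the genome of the budding yeast Saccharomyces cerevisiae by chromatin immunoprecipitation followed by hybridisation to tiling microarrays (ChIP-chip). Cells grown on raffinose, a sugar that neither induces nor strongly represses the galactose genes, were arrested for 3 hours with alpha factor, the mating pheromone that holds MATa cells in G1. They were sampled before galactose was added (0 min, 2 arrays) and 60 min after the shift to galactose (2 arrays). On each array an immunoprecipitate of RNA polymerase II (Pol II) was hybridised together with genomic DNA. Each array carried 41775 probes outside the control spots, with a median spacing of 257 bp, and 30279 of them lay inside 5492 named ORFs. Over 99.9% of the probes stood well above background in either channel on every array, with the lowest share being 99.91%, and the number of arrays limits the precision. The labels number the replicates but do not say whether they came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

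Values are log2 of Cy3 over Cy5 with the array median at 0, unless a single dye or a correlation is named. This is the direction of the deposited value table and is opposite to the dyes in the labels. The labels place the immunoprecipitate in Cy5 and genomic DNA in Cy3, and with those dyes every log2 ratio and difference of ratios changes sign while sizes, errors and p-values stay as given. The labelled dyes do not match the channel values: over the 6 called GAL genes the median change was 3.94 in log2 Cy3 and -0.66 in log2 Cy5. The direction used here rests on this, on the deposited ratio itself and on a wider spread of log2 Cy3 (SD 1.01 to 1.17 across probes) than of log2 Cy5 (SD 0.75 to 0.83) on 4 of 4 arrays. Since the galactose genes helped to choose it, their sign is not independent evidence of the direction.

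The comparison asks which genes gained or lost Pol II between 0 min and 60 min after the shift to galactose. No array was made at 60 min without galactose. An effect of galactose therefore cannot be told apart from one of the time that passed. The genes of galactose uptake and breakdown changed most. GAL7, GAL10 and GAL1, which encode the enzymes of the Leloir pathway, and GAL2, the galactose permease, rose by 4.41 to 5.63 on the log2 scale. GAL7 went from -1.43 ± 0.01 (SD, n = 2) at 0 min to 4.20 ± 0.18 (SD, n = 2) at 60 min, a 49.6-fold difference. GAL2 rose 47.4-fold, from -1.19 ± 0.16 to 4.37 ± 0.44, GAL10 rose 28.3-fold, from -0.96 ± 0.02 to 3.86 ± 0.20, and GAL1 rose 21.2-fold, from -0.34 ± 0.07 to 4.07 ± 0.44. The regulators followed with smaller changes. GAL3, the galactose sensor, rose 5.63-fold, from -0.55 ± 0.01 to 1.95 ± 0.11, and GAL80, the repressor of Gal4, rose 4.54-fold, from -0.19 ± 0.06 to 1.99 ± 0.18. The limma adjusted p of these 6 genes lay between 0.00121 for GAL7 and 0.0188 for GAL80. With loess within arrays the calls of GAL3 and GAL80 were lost at differences of 1.60 and 1.59, against 2.49 and 2.18 (limma adjusted p = 0.0904 and 0.453, between 1.18e-07 and 0.998 over all alternatives of GAL3 and between 8.89e-07 and 0.998 over those of GAL80), and with Cy5 alone no gene was called. The 0.998 of both genes came from Cy5 alone. In the reported direction Cy5 holds genomic DNA, so that setting does not test a change of Pol II. At 60 min, 1 probe each of GAL7, GAL10 and GAL1 and 2 probes of GAL2 were saturated in Cy3 on at least 1 array. Saturation in Cy3 lowers the folds of these 4 genes. Their log2 Cy5 also changed, between -0.89 (GAL1) and -0.52 (GAL10), which raises the ratio. In log2 Cy3 alone they rose by 3.55 (GAL1) to 4.81 (GAL7). The folds are therefore read neither as exact nor as limits. With the labelled dyes the same 6 genes fell by these amounts.

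**Figure D1:**
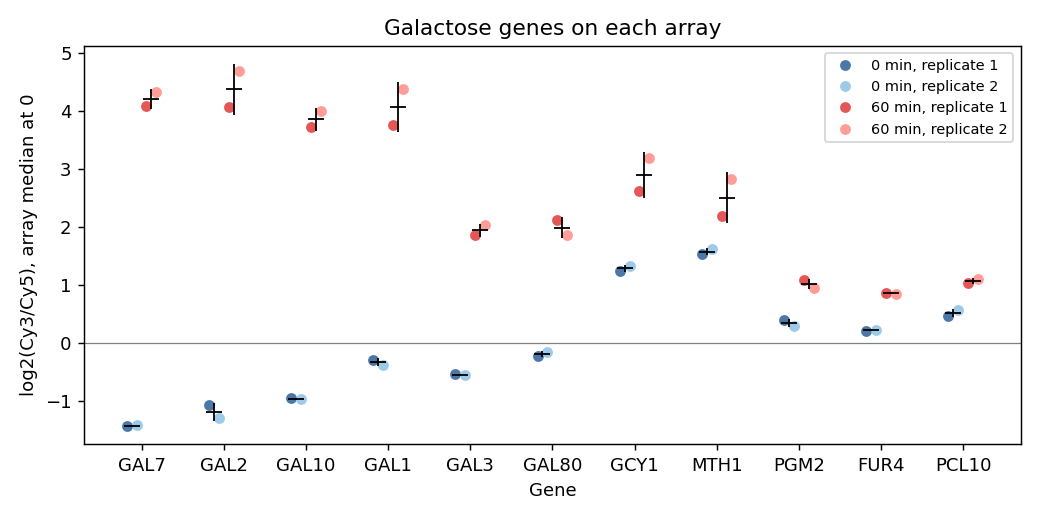
Log2(Cy3/Cy5) of the 11 members of the galactose list on each of the 4 arrays (points), with the mean and SD of each time point in black (n = 2). Both 60 min values lie above both 0 min values for all 11 genes, and 6 of them passed the test.

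The other 5 members of the galactose list did not pass the test over all ORFs with all 4 arrays and no block. GCY1 and MTH1 passed with replicate number as a block, though the numbers are not known to pair the samples. With Cy3 alone 10 of the 11 members passed, in a setting that called 170 ORFs and was chosen after seeing the data. GCY1, a glycerol dehydrogenase, differed by 1.61 (SE 0.21, limma adjusted p = 0.134), and MTH1, a regulator of glucose transporter genes, by 0.93 (0.62 to 1.24 with 1 array left out, SE 0.23, limma adjusted p = 0.256). PGM2, the major phosphoglucomutase, differed by 0.67, FUR4, the uracil permease whose gene lies beside GAL1, by 0.63, and PCL10, a cyclin of the Pho85 kinase, by 0.55 (limma adjusted p = 0.179, 0.172 and 0.222). In the list of 11 genes fixed before the data were examined, 6 rose at the threshold over all ORFs, and 11 rose when adjusted over the list alone. As a set the list rose with a median of 2.18 (camera adjusted p = 5.51e-20), with an adjusted p = 0.233 with an estimated correlation.

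Across all 5492 ORFs, limma called 7 higher and 0 lower at 60 min at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 356 higher and 399 lower, against 275 in both directions together that chance gives. Both 60 min values lay above both 0 min values for 1242 ORFs and below them for 1377, 48.0% of the 5451 measured on all 4 arrays, where chance gives 33.3%. The gene outside the galactose list was FAR1, the inhibitor of the G1 cyclin-dependent kinase that acts in pheromone arrest. FAR1 rose 2.93-fold, from 1.78 ± 0.06 to 3.33 ± 0.04 (SD, n = 2; limma adjusted p = 0.0263). Its call was lost in 7 of the alternatives. In 3 of them the difference stayed near 1.55: without 0 min replicate 1 (1.51, limma adjusted p = 0.131), without 0 min replicate 2 (1.59, limma adjusted p = 0.0996) and with trend and robust (1.55, limma adjusted p = 0.113). It was smaller with loess (1.12), quantile normalization (1.22), arrays scaled to 1 spread (1.04) and Cy5 alone (0.48). Cy5 alone, where its limma adjusted p was 0.998, does not test a change of Pol II in the reported direction. Over all 20 alternatives its adjusted p ranged from 6.34e-05 to 0.998. The counts depended on the arrays at 60 min: without replicate 1 of that time point 333 ORFs were called and without replicate 2 there were 1798, since the lone array is then assumed to vary as little as the pair at 0 min.

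At single probes, 40 of 41673 were called by limma, all of them higher at 60 min, with 1085 higher and 1341 lower at an unadjusted p under 0.05. Of these 40, 23 lay inside GAL1, GAL10, GAL7, GAL2, GAL3 or GAL80, and 16 lay outside these ORFs but at most 1157 bp from their probes. On chromosome 2, in the coordinates of the array files, whose genome build is not given in the sources used here, the called probes ran from 273828 in the promoter of KAP104 past GAL7, GAL10 and GAL1 to 281161 in the promoter of FUR4. On chromosome 12 they ran from EMP46 at 288977 across GAL2 to 292375 downstream of SRL2, and on chromosome 4 from GAL3 at 464402 to 465315 in the promoter of SNQ2. The 1 called probe farther away lay at 255628 to 255687 on chromosome 2, between HHF1 and HHT1, a divergent pair of histone H4 and H3 genes, and was 3.97 higher at 60 min. This locus was singled out after its values were seen. The single probe inside HHT1 differed by 3.68 (SE 0.29, limma adjusted p = 0.0549). No difference is read for the other H3 gene HHT2, whose probe was saturated in Cy5 on all 4 arrays and in Cy3 on 1 of those at 60 min.

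**Figure D2:**
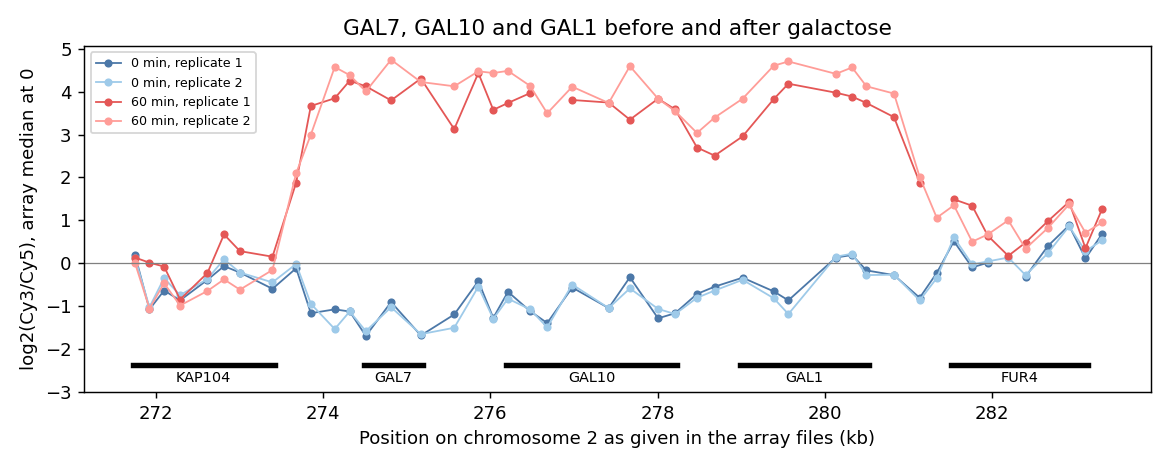
Log2(Cy3/Cy5) of each probe (points) along the GAL7, GAL10 and GAL1 region of chromosome 2 on the 4 arrays, with black bars spanning the probes inside each ORF. The 60 min arrays lie above the 0 min arrays from the promoter of KAP104 to that of FUR4. They also lie above them inside FUR4, by less (differences of 0.34 to 0.99). Inside KAP104 the differences run from -0.11 to 0.53.

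**Figure D3:**
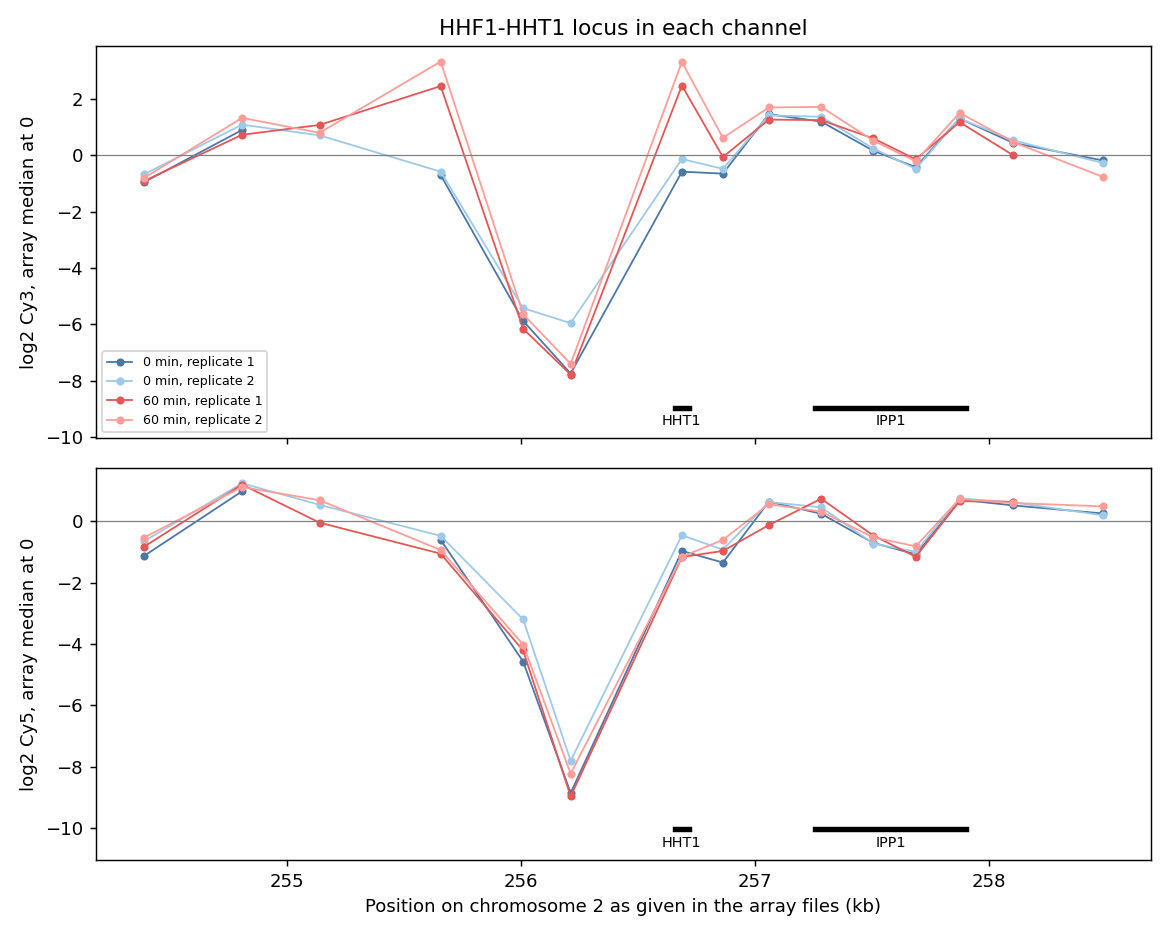
Log2 Cy3 (top) and log2 Cy5 (bottom) of each probe around HHF1 and HHT1 on the 4 arrays, with the array median at 0 and black bars spanning the probes inside each ORF. A pair of probes at 255980 and 256183 is dim in both channels on all 4 arrays, and the probes on both sides of them are brighter in Cy3 at 60 min.

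Among 31 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 called 16, 10 higher and 6 lower at 60 min. None of the 16 was called with an estimated correlation, where the lowest adjusted p = 0.233 with an estimated correlation and 6 lists had an unadjusted p under 0.05. On 4 arrays this version of camera has few residual degrees of freedom and little power. A call lost there does not show that correlation between genes made it. The pheromone list had an estimated correlation of -0.011, below the preset, yet its unadjusted camera p went from 2.38e-12 to 0.0149. fry, which asks whether the genes of a set move one way on balance, called 6 lists: galactose, ribosome biogenesis, pheromone response, TCA cycle, methionine and sulfur, and hexose transport. The spread of the ratio across ORFs was wider at 60 min (SD 0.87 and 0.92) than at 0 min (SD 0.74 and 0.76), and 7 of the 16 lists kept both call and direction when all arrays were scaled to 1 spread, a setting chosen after seeing the data. The 7 were the galactose, TCA cycle, ribosome biogenesis, RNA polymerase I and III, chaperone, methionine and cell wall lists. With Cy5 alone 3 lists were called, 2 of them among the 16 (galactose and subtelomeric). Such calls do not speak for a change of Pol II, since Cy5 holds genomic DNA in the reported direction. Of 71 genes examined one by one, the members of the galactose list, FAR1 and up to 4 members of each called list, the difference of 23 moved by over 1.5 times when 1 array was left out. With the labelled dyes the higher and lower lists trade places.

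Ribosome biogenesis genes, which encode factors that process and assemble ribosomes, rose as a set by a median of 0.23 over 116 members (camera adjusted p = 3.12e-13; adjusted p = 0.233 with an estimated correlation). Both 60 min values lay above both 0 min values for 78 of the 116 and below them for 5. In both directions together, 48.0% of all ORFs measured on all 4 arrays did not overlap, and chance gives 33.3%. In limma 0 members passed over all ORFs (31 higher and 1 lower at an unadjusted p under 0.05), and 1, RIO1, rose when adjusted over the list alone. RIO1, a kinase of small subunit maturation, differed by 1.16 (limma adjusted p = 0.0714), IMP4 by 0.58, the nucleolar methyltransferase NOP1 by 0.54 and KRI1 by 0.46 (0.23 to 0.70 with 1 array left out). The subunits of RNA polymerases I and III rose as a set by a median of 0.27 over 24 members (camera adjusted p = 6.5e-05; adjusted p = 0.485 with an estimated correlation), with 0 members past limma's threshold over all ORFs and 0 adjusted over the list alone (4 higher and 0 lower at an unadjusted p under 0.05). Among them RPA12 differed by 0.67 (0.19 to 1.16 with 1 array left out), RPA135 by 0.50, RPA190 by 0.47 and RPA14, measured on 1 array at 60 min, by 0.44 (0.25 to 0.64). The median of the list was 0.16 without 60 min replicate 1 and 0.42 without 60 min replicate 2.

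Genes of the TCA cycle rose as a set by a median of 0.50 over 17 members (camera adjusted p = 1.61e-10; adjusted p = 0.233 with an estimated correlation), with 0 members past limma's threshold over all ORFs (12 higher and 0 lower at an unadjusted p under 0.05) and 11 higher adjusted over the list alone. The call held at smaller medians of 0.21 with loess, 0.23 with quantile normalization and 0.20 with arrays scaled to 1 spread. SDH1, a subunit of succinate dehydrogenase, differed by 0.85 (SE 0.10), aconitase ACO1 by 0.78 (SE 0.12), and the isocitrate dehydrogenase subunits IDH1 and IDH2 by 0.77 and 0.66 (IDH2 0.43 to 0.88 with 1 array left out). The respiratory chain and ATP synthase list rose by a median of 0.40 over 33 members (camera adjusted p = 3.52e-10; adjusted p = 0.233 with an estimated correlation), with 0 past limma's threshold over all ORFs (15 higher and 0 lower at an unadjusted p under 0.05) and 5 higher adjusted over the list alone, and lost its call with arrays scaled to 1 spread (median 0.03, against 0.08 with loess and 0.11 with quantile normalization, where it was called). ATP20, measured on 1 array at 60 min, differed by 0.88, ATP4 by 0.72 (0.35 to 1.09 with 1 array left out), QCR10 by 0.69 (0.23 to 1.14) and COX12 by 0.59 (0.28 to 0.90).

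Chaperone genes of the heat shock factor Hsf1 rose as a set by a median of 0.42 over 23 members (camera adjusted p = 5.91e-11; adjusted p = 0.292 with an estimated correlation), with 0 past limma's threshold over all ORFs (14 higher and 0 lower at an unadjusted p under 0.05) and 10 higher adjusted over the list alone. The call held at smaller medians of 0.24 with loess, 0.24 with quantile normalization and 0.18 with arrays scaled to 1 spread. HSP82 differed by 0.71 (SE 0.11), the mitochondrial chaperonin HSP60 by 0.67, YDJ1 by 0.65 and SSA1 by 0.63. Pheromone response genes rose as a set by a median of 0.35 over 34 members, which turned to -0.03 without a call when arrays were scaled to 1 spread and stood at 0.04 with loess and 0.06 with quantile normalization, also without a call (camera adjusted p = 1.84e-11; adjusted p = 0.233 with an estimated correlation), with 1 member, FAR1, past the threshold over all ORFs and 12 adjusted over the list alone. FUS2, which acts in cell fusion, differed by 0.63, CIK1 by 0.55 and SST2, a regulator of pheromone desensitisation, by 0.53.

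The direction of the cytosolic ribosomal protein genes flips with the scaling. Their 128 members rose as a set by a median of 0.24 (camera adjusted p = 2.48e-15; adjusted p = 0.445 with an estimated correlation), but with arrays scaled to 1 spread the median was -0.19 and was called in the opposite direction (camera adjusted p = 2.9e-08). With quantile normalization it was -0.07 and also called in the opposite direction (camera adjusted p = 0.02). With loess it was -0.02 without a call. In limma 0 members passed over all ORFs and 0 adjusted over the list alone, with 32 higher and 0 lower at an unadjusted p under 0.05. RPL32 differed by 0.62 (0.32 to 0.93 with 1 array left out), RPS30A by 0.62 (0.32 to 0.92), RPS24B by 0.59 (0.26 to 0.91) and RPL33B by 0.57 (0.36 to 0.79). Translation factors rose by a median of 0.29 over 32 members (camera adjusted p = 3.81e-06; adjusted p = 0.233 with an estimated correlation), and genes of amino acid biosynthesis under Gcn4 by 0.11 over 53 members, which turned to -0.06 with arrays scaled to 1 spread and to -0.02 with quantile normalization (camera adjusted p = 0.00519; adjusted p = 0.543 with an estimated correlation). In limma 0 members of either passed over all ORFs, with 8 and 10 higher and 0 and 1 lower at an unadjusted p under 0.05, and adjusted over the list alone 0 and 3 rose. Both lists lost their calls with arrays scaled to 1 spread and with quantile normalization. Translation factors stood at 0.04 and 0.10 there, and at 0.11 with loess, where they were called. The Gcn4 list also lost its call with loess and without 60 min replicate 2, where its median was -0.01, against 0.19 without 60 min replicate 1. SUI1, measured on 1 array per time point, differed by 1.25, HYP2 by 0.61 (0.11 to 1.10 with 1 array left out, and -0.02 with arrays scaled to 1 spread), RLI1 by 0.45 (0.22 to 0.68) and EFT1 by 0.45 (0.23 to 0.66). CPA1, a gene of arginine synthesis, differed by 1.48 (limma adjusted p = 0.16), ILV2 by 0.60 and LEU9 by 0.43.

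Methionine and sulfur assimilation genes fell as a set, with a median of -0.31 over 23 members (camera adjusted p = 1.83e-06; adjusted p = 0.233 with an estimated correlation), and both 60 min values lay below both 0 min values for 18 of the 23. In limma 0 members passed over all ORFs and 0 adjusted over the list alone, with 0 higher and 9 lower at an unadjusted p under 0.05. MET17, the O-acetylhomoserine sulfhydrylase, differed by -0.52 (-0.84 to -0.21 with 1 array left out, and with 1 probe saturated in Cy5), the sulfate permease SUL1 by -0.51, SAM2 by -0.42 and MET32 by -0.41. The median of the list was -0.19 with loess. Cell wall genes fell as a set, with a median of -0.23 over 31 members (camera adjusted p = 0.00596; adjusted p = 0.695 with an estimated correlation), with 0 members past limma's threshold over all ORFs and 0 adjusted over the list alone (1 higher and 10 lower at an unadjusted p under 0.05). The median turned to 0.02 without 60 min replicate 1, and was -0.46 without 60 min replicate 2, -0.43 with arrays scaled to 1 spread, -0.35 with quantile normalization, and -0.06 without a call with Cy3 alone. PIR3 differed by -0.81 (-1.16 to -0.45 with 1 array left out), YPS3 by -0.67 (-0.996 to -0.346), DAN1 by -0.67 and TIR2 by -0.64.

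The other 4 lists that fell lost their calls with arrays scaled to 1 spread and with quantile normalization, and kept them with loess. Hexose transporters fell with a median of -0.24 over 14 members (camera adjusted p = 0.000622; adjusted p = 0.233 with an estimated correlation), meiosis genes with -0.19 over 49, which turned to 0.02 with quantile normalization (camera adjusted p = 0.000102; adjusted p = 0.445 with an estimated correlation), G1/S genes of SBF and MBF with -0.15 over 55 (camera adjusted p = 0.00358; adjusted p = 0.454 with an estimated correlation) and subtelomeric families with -0.31 over 7 (camera adjusted p = 0.00596; adjusted p = 0.445 with an estimated correlation). In the same order, the medians were -0.10, -0.05, -0.06 and -0.21 with arrays scaled to 1 spread. They were -0.09, 0.02, -0.04 and -0.19 with quantile normalization and -0.12, -0.10, -0.08 and -0.19 with loess. In proportion to its size, though not in log2 units, the subtelomeric median shrank least of these in each of the settings. In limma 0 of their members passed over all ORFs, with 4, 11, 9 and 1 lower and 0, 1, 1 and 0 higher at an unadjusted p under 0.05. Adjusted over the list alone, 2 hexose transporters (HXT11 and HXT14) and 1 subtelomeric gene (COS12) fell, and 0 of the meiosis and G1/S genes. The calls were also lost for the G1/S list without 0 min replicate 2 (median -0.09, and -0.10 with the call kept without 60 min replicate 1), and for hexose transporters (-0.28), meiosis genes (-0.16) and subtelomeric families (-0.34) without 60 min replicate 2. Subtelomeric families lost it with Cy3 alone too (-0.15), and stood at -0.47 without 0 min replicate 2. HXT4 differed by -0.85 (-1.21 to -0.49 with 1 array left out), HXT11 by -0.71, HXT14 by -0.71 and HXT13, measured on 1 array at 0 min and in the opposite direction, by 0.66. SPO11, AMA1, MEI5 and SPO69 differed by -0.76, -0.68, -0.63 and -0.56. In the G1/S list SRL1 differed by 0.86 (0.52 to 1.20 with 1 array left out), against CLB6 at -0.65, TOS4 at -0.49 (-0.67 to -0.32) and CLB5 at -0.47. COS12 was 2.01-fold lower, COS10 differed by -0.40 (-0.55 to -0.24 with 1 array left out), COS1 by -0.35 (-0.59 to -0.11) and COS9 by -0.31, and near-identical copies of such families may share probe signal.

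The remaining 15 lists were not called. They comprised glycolysis (median 0.01), gluconeogenesis and C2 metabolism (-0.04), sucrose and maltose use (0.22), MATalpha-specific genes (-0.29), histones (0.04), the CLB2 cluster (0.00) and M/G1 genes (0.04). The rest were environmental stress genes (-0.05), phosphate (0.05), nitrogen catabolite (-0.05), iron (-0.03), ergosterol (0.04), the proteasome (0.09), Pol II and Mediator subunits (-0.04) and mitochondrial ribosomal proteins (0.05). The histone list holds the linker histone HHO1 beside core histones, and HHT2, for which no difference is read. Leaving out 1 array moved 13 of these 15 medians by over 1.5 times, for sucrose and maltose use to between 0.08 and 0.24, phosphate 0.07 and 0.17, the proteasome 0.04 and 0.14, stress genes -0.14 and -0.02 and mitochondrial ribosomal proteins 0.00 and 0.07. The set means of glycolysis (-0.10), gluconeogenesis (0.14), M/G1 (-0.01) and Pol II and Mediator subunits (0.01) had the sign opposite to their medians, and camera's direction was lower for glycolysis and higher for the other 3. Their members past the threshold over all ORFs numbered 0. Adjusted over the list alone, HHT1, SUR7 of the CLB2 cluster (1.71, limma adjusted p = 0.0714 over all ORFs), the lactate transporter JEN1 (0.95), SAG1 (0.56) and the ornithine transaminase CAR2 (0.74) rose. MF(ALPHA)1 (-0.52), MF(ALPHA)2 (-0.44), the allantoin permease DAL4 (-0.94) and DAL1 (-0.49) fell. With arrays scaled to 1 spread 3 of the 15 lists were called: glycolysis (median -0.37, camera adjusted p = 1.33e-05), stress genes (-0.10, camera adjusted p = 0.02) and the CLB2 cluster (0.08, camera adjusted p = 0.0204). The same 3 were called with quantile normalization. Glycolysis was also called at -0.21 with loess, at -0.13 with Cy5 alone, at -0.10 without 0 min replicate 1 and at -0.27 without 60 min replicate 2, but at 0.21 without 60 min replicate 1 (camera adjusted p = 0.0345), where ergosterol genes (0.12) and mitochondrial ribosomal proteins (0.07) were called too.

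The occupancy levels show where Pol II stood within each time point. The cytosolic ribosomal protein genes had the highest list median at 0 min, 2.11 ± 0.02 (SD, n = 2), and stood at 2.36 ± 0.14 at 60 min. With the labelled dyes it would be the lowest. Glycolysis stood at 1.96 ± 0.29 and 1.94 ± 0.47, pheromone response at 1.75 ± 0.03 and 2.05 ± 0.04, and the respiratory chain at 1.61 ± 0.02 and 2.02 ± 0.13, each above all 10000 random lists of equal size at both times. Meiosis genes stood at -0.67 ± 0.03 and -0.80 ± 0.09, below all 10000. The galactose list moved from -0.19 ± 0.06, at percentile 13.3 of the random lists, to 2.51 ± 0.44, above all of them. With the labelled dyes these ranks turn too, and above and below trade places. With Cy5 alone, its sign turned to match, the ribosomal protein level at 0 min was 0.41, below the histone list at 0.42. The others were 0.27 for glycolysis, 0.13 for pheromone response, 0.04 for the respiratory chain, 0.04 for meiosis and 0.09 for the galactose list.

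**Figure D4:**
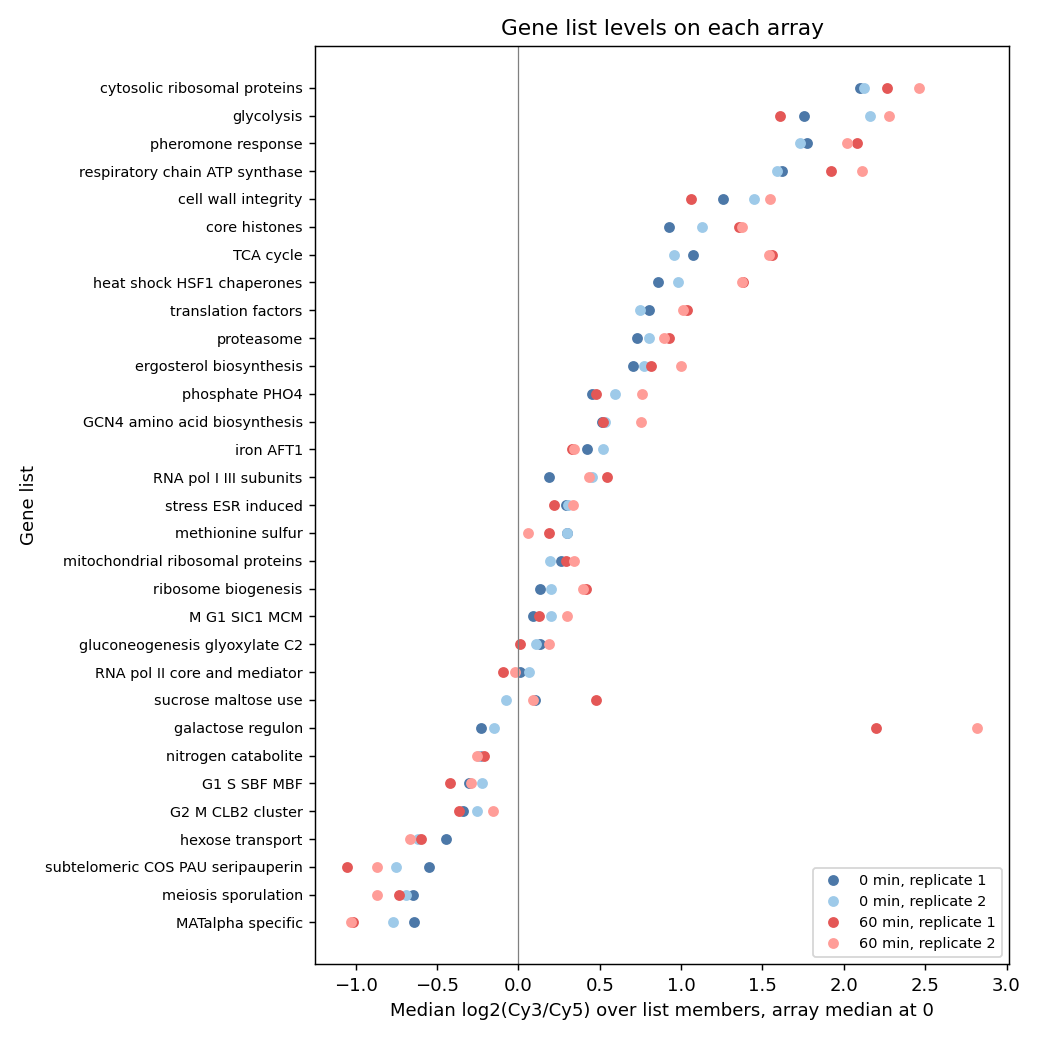
Median log2(Cy3/Cy5) of each of the 31 gene lists on the 4 arrays (points), ordered by the mean at 0 min, with the array median at 0. The galactose list moves from -0.19 at 0 min to 2.51 at 60 min.

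The 10 ORFs with the highest mean at 0 min were HSP150 (3.76), the alpha factor receptor STE2 (3.63), the agglutinin subunit AGA1 (3.62), SED1 (3.62), RPL28 (3.38), glyceraldehyde phosphate dehydrogenase TDH3 (3.30), RPL3 (3.22), pyruvate decarboxylase PDC1 (3.20), RPL10 (3.13) and ILV5 (3.04). The 10 at 60 min, in no order, were GAL2 (4.37), GAL7 (4.20), carbonic anhydrase NCE103 (4.17), STE2 (4.13), AGA1 (4.10), GAL1 (4.07), GAL10 (3.86), RPL28 (3.46), RPL3 (3.39) and TDH3 (3.39), and 5 ORFs stood in both groups of 10. Their order at 60 min is not read, since 3 probes of AGA1, 2 of GAL2 and 1 each of GAL7, GAL1 and GAL10 were saturated in Cy3 there. NCE103 differed by 2.39 between the times (SE 0.30, limma adjusted p = 0.125). With the labelled dyes these ORFs would be the lowest, not the highest.

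By the position classes of the array files, the median over nuclear probes inside ORFs was -0.05 ± 0.01 (SD, n = 2) at 0 min and -0.04 ± 0.02 at 60 min. Probes downstream of ORFs stood at 0.54 ± 0.01 and 0.65 ± 0.01, promoter probes at 0.25 ± 0.01 and 0.26 ± 0.02, and divergent promoters at -0.09 ± 0.03 and -0.22 ± 0.04. Along ORFs of at least 1500 bp, with the span of their probes divided into 3 equal parts, the 3′ part exceeded the 5′ part by a median of 0.17 at 0 min and 0.25 ± 0.03 at 60 min. limma called 0 of 2144 ORFs for a change of this difference, with 45 higher and 5 lower at an unadjusted p under 0.05. Together these are fewer than chance gives at that threshold, so their split is not read as a direction. Without 60 min replicate 1 the count was 11 and without replicate 2 it was 804, with the lone array again assumed to vary like the pair at 0 min.

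Replicate agreement was closer at 0 min than at 60 min. Across ORFs, which are not independent replicates, Pearson's r was 0.984 between the arrays at 0 min and 0.917 between those at 60 min, with Spearman's rho of 0.979 and 0.894. The SD of the replicate differences was 0.137 at 0 min and 0.366 at 60 min. Replicate 2 at 60 min correlated more closely with the arrays at 0 min (r = 0.944 and 0.943) than with its own replicate.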

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

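The settings Cy3 alone, scale between arrays, crossed replicate numbers and without mitochondrial probes were chosen after seeing the data, as was the reported orientation; the others were planned. Cy5 alone is shown with its sign turned to match. The cause was not tested for any value here unless stated. The median of the galactose list kept its direction and call in every setting but the turned sign, from 0.197 with Cy5 alone to 2.60 with normexp. In the reported direction Cy5 holds genomic DNA, so the call with Cy5 alone does not speak for a change of Pol II. Its members FUR4, GCY1 and MTH1 changed sign there. No slide or scan block was run, since all arrays share 1 slide and 1 scan. With the sign turned to the labelled dyes, as planned, 0 ORFs were higher and 7 lower, the galactose median was -2.18, and all other ratios turn by construction.

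With normexp, 13 ORFs were called (13 higher), the ribosomal protein level at 0 min was 2.60, and replicate r was 0.923 at 60 min and 0.982 at 0 min. With Cy5 alone, 0 ORFs were called by limma (0 higher; at an unadjusted p under 0.05, 61 higher and 66 lower), 0 galactose genes and 3 lists, and that level was 0.41. With Cy3 alone, 170 ORFs were called (89 higher, 81 lower), 10 galactose genes passed, and that level was 1.71. Leaving out each array in turn gave 7 to 1798 ORFs (7 to 854 higher, 0 to 944 lower), 6 to 11 galactose genes, 13 to 18 lists, 58 to 19316 probes and 0 to 804 ORFs for the difference along genes; the highest counts of ORFs and probes came without 60 min replicate 2, where the lone array is assumed to vary like the others.

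With the replicate block, 82 ORFs (51 higher, 31 lower), 8 galactose genes and 168 probes were called. The numbers are not known to pair the samples: same-numbered arrays deviated with a correlation of -0.237 across ORFs. With crossed replicate numbers as the block, 18 ORFs were called, 18 higher, with 7 galactose genes.

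Median differences of lists, or differences of genes, that changed sign follow by setting. With normexp: glycolysis -0.11, gluconeogenesis 0.023 and ergosterol -0.038. With loess: glycolysis -0.207, histones -0.066, iron 0.023, ergosterol -0.032, Pol II and Mediator 0.019 and ribosomal proteins -0.017. With quantile normalization: glycolysis -0.307, MATalpha 0.067, meiosis 0.02, histones -0.152, Gcn4 -0.024, nitrogen 0.018, ergosterol -0.099, proteasome -0.044, Pol II and Mediator 0.035, ribosomal proteins -0.068, mitochondrial ribosomal proteins -0.01 and MEI5 0.104. With outlier flags kept: glycolysis -0.011. With at least 3 probes per ORF: glycolysis -0.045, CLB2 cluster -0.011 and Pol II and Mediator 0.04. With the median over probes: glycolysis -0.044 and gluconeogenesis 0.006. With Cy5 alone: hexose transport 0.013, glycolysis -0.126, gluconeogenesis 0.014, meiosis 0.005, stress 0.002, nitrogen 0.057, iron 0.033, ergosterol -0.032, ribosomal proteins -0.035, mitochondrial ribosomal proteins -0.021, FUR4 -0.374, GCY1 -0.135, MTH1 -0.018, HXT4 0.272, IDH2 -0.001, NOP1 -0.155, RPA190 -0.068, AMA1 0.065, MEI5 0.042, CLB6 0.038, SSA1 -0.016, SUL1 0.054, SAM2 0.03, DAN1 0.036 and COS10 0.018. With Cy3 alone: gluconeogenesis 0.054, histones -0.079, M/G1 -0.003 and Pol II and Mediator 0.015. With scaling between arrays: glycolysis -0.371, pheromone -0.03, histones -0.219, Gcn4 -0.059, nitrogen 0.01, ergosterol -0.116, proteasome -0.08, Pol II and Mediator 0.023, ribosomal proteins -0.191, mitochondrial ribosomal proteins -0.021 and HYP2 -0.024. Leaving out each array in turn gave glycolysis -0.274 to 0.212, histones -0.157 to 0.153, CLB2 cluster -0.039 to 0.11, M/G1 -0.002 to 0.069, iron -0.084 to 0.038, gluconeogenesis -0.057 to 0.133, cell wall -0.464 to 0.02, Gcn4 -0.01 to 0.19, ergosterol -0.113 to 0.123 and Pol II and Mediator -0.023 to 0.038.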

Other observations

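All tests of explanations here were chosen only after the result was seen. Some probes were far dimmer than the array median in both dyes. Of all probes, 128 lay over 3 log2 below the array median in both channels on all 4 arrays, of which 73 still stood well above background in both channels on all 4. On nuclear chromosomes the 128 formed 14 runs of at least 2 neighbouring probes. Of the 7 probes inside BAR1, which encodes the protease that degrades alpha factor, 6 were among them, with log2 Cy5 between -9.22 and -2.78 relative to the array median over all 7. Another run of 10 probes spanned HXT7 and HXT6 from 1157748 to 1159553 on chromosome 4, and 2 probes fell in HMLALPHA1. Probes of mitochondrial DNA (295) had a median ratio of 0.42 and 0.44 at 0 min but -0.39 and 1.40 at 60 min, so they differed between the replicates at 60 min more than between the times.

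The direction of the ratio bears on the sign of every ratio. If the immunoprecipitate were in Cy5, as labelled, the Cy5 signal of the galactose genes would carry the change. Over the 6 called GAL genes, however, the median change was -0.66 in log2 Cy5 and 3.94 in log2 Cy3, with the larger change in Cy3 for 6 of 6, which argues against the labelled dyes. Log2 Cy3 also spread more across probes than log2 Cy5 on 4 of 4 arrays, a test that did not use the galactose genes and is consistent with the immunoprecipitate in Cy3, as the deposited ratio reads. The data cannot show where the dyes were exchanged, and an exchange in the labels and a reversed labelling at the bench remain open.

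The HHF1 and HHT1 locus differed from its surroundings. The probes at 255980 and 256183 on chromosome 2 lay between -8.96 and -3.20 in log2 Cy5 relative to the array median, while the flanking probes were higher at 60 min by 3.97 and 3.68. The probe of the paralog HHT2 differed by -0.24 in log2 Cy3 on the 1 array at 60 min where it was not saturated, which is too few to exclude HHT2 signal on the HHT1 probe there. At 0 min the HHT2 probe already stood at 3.80 and 4.29 in log2 Cy3, and the HHT1 probe at -0.58 and -0.13. HHT2 signal thus did not make the HHT1 probe bright on the arrays at 0 min. Probes that hybridise poorly whatever the DNA, as dim as 0.306% of all probes, cannot be told apart from missing DNA without a strain known to hold the segment. That the strain lacks this promoter segment and carries a galactose-responsive promoter in its place, which may be a strain construct, is a hypothesis prompted by these values, which do not test it.

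The gene lists tended to shift away from the middle: across the 31 lists the Spearman correlation of the level at 0 min with the median difference was 0.55, and 0.632 without the galactose list, with lists that share chance values of the same arrays. A wider range of the ratios on the 60 min arrays would give this. With arrays scaled to 1 spread, 7 of the 16 called lists kept call and direction, which argues against the range as the whole cause for those of them that rose. Of the 7, the median shrank for the TCA cycle (0.50 to 0.20), chaperones (0.42 to 0.18), ribosome biogenesis (0.23 to 0.16) and RNA polymerases I and III (0.27 to 0.18). It did not shrink for the methionine (-0.31 to -0.33) and cell wall (-0.23 to -0.43) lists. Scaling could not take the call of these falling lists away. They stood above 0 at 0 min (0.30 and 1.35), where scaling to 1 spread lowers the difference. A wider range would raise lists above 0, and these fell, though the cell wall median turned to 0.02 without 60 min replicate 1. The other 9 lost the call or turned, and for them a wider range from the hybridisation cannot be told apart from a real widening of Pol II occupancy, because the range differs with the time point. The galactose list stands apart, with 6 of its 11 members past the threshold one by one. For the other 6 of the 7 lists a biological response to galactose remains a hypothesis. None of the 7, the galactose list included (camera adjusted p = 0.233), was called at an estimated correlation.

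The arrays at 60 min differed in both dyes. The SD of the replicate difference across ORFs was 0.245 in Cy3 and 0.222 in Cy5 at 60 min, against 0.159 and 0.162 at 0 min. The Cy3 and Cy5 differences between replicates correlated across ORFs at 0.638 at 0 min and at -0.228 at 60 min.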
